A study of Sus scrofa with 18 samples.

How the data were processed

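The series holds pig spermatogonia, pachytene spermatocytes and round spermatids, with 3 RNA-seq and 3 MeRIP-seq libraries of each. Per the labels' protocols, total RNA from high-purity cell fractions was depleted of ribosomal RNA for directional RNA-seq, poly(A) RNA was immunoprecipitated for m6A with a commercial kit, and all libraries were sequenced as 150 bp pairs on an Illumina instrument. The purity of the fractions, the number of animals and what a replicate number stands for are not given in the sources used here.

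The authors deposited 1 expression table with a pair of columns for each RNA-seq library and 9 lists of peaks on mRNA, 1 for each MeRIP-seq library. Per the labels' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned to the susScr3 build with HISAT2 2.0.4, and expression came from Cufflinks and Cuffdiff, without a version. The deposited FPKM (fragments scaled by transcript length and library size) hold 1 value per gene and library, and their column totals are not constant. The second kind of column, headed as counts, holds the authors' estimated counts, scaled by a factor for each library. Peaks were called with MACS, per the labels' protocols, without a version. Libraries were made with and without immunoprecipitation, per the same protocols, and which of them served as background is not given. The peak lists hold, per the file headers, coordinates, a fold enrichment (the ratio of the authors' peak signal to background), a score scaled from minus log10 of the p-value, which is capped, and a false discovery rate in percent. Listed peaks start at a deposited score of 50.0 and reach deposited false discovery rates of 100 percent, and all were kept. The annotation used by the authors is not given in the sources used here.

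The sample columns were matched to the libraries by the short names in the labels, and 0 were left unmatched. Each library's estimated counts were whole multiples of 1 step (0.885 to 1.15) for 99.7% to 99.8% of values above 0, within 0.02 of a fragment, and division by the step gave whole fragments. The libraries held 3535062 to 5410510 such fragments. Of 19442 genes 13088 were named in the table, 1528 further genes through a table of gene IDs, 39 through the peak lists, and 4787 kept their Ensembl ID, and genes of the same symbol were summed, which left 19115.

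The planned test was limma on log2 FPKM, or edgeR if the table held counts. Since fragments could be recovered, edgeR was used, and limma on log2(FPKM + 1) became an alternative chosen after the data were seen. The test was edgeR 4.0.16 (quasi-likelihood, legacy fit, TMM scaling) on all 9 libraries for genes of at least 1 FPKM in 3 or more libraries (13698 genes), with the 3 cell types as groups and no replicate block. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold change of at least 2. The common biological coefficient of variation was 0.344. In data simulated at this depth and spread, 200 of 13698 genes were changed. Of 4-fold changes 74% to 81% were called, and 9% to 13% of 2-fold changes had an edgeR adjusted p below 0.05. Of 91 to 96 calls 4 to 7 were false. In the real comparisons far more genes, 4113 to 6971, had an adjusted p below 0.05, and the simulation held no library unlike the others of its type. Its rates therefore do not carry over to the real comparisons. A gene that was not called may still have changed 2-fold. SE is that of the log2 fold change in the fit. Genes without fragments in a group are given as a lower bound against a floor of 3 fragments over the group, and genes with 1 to 3 fragments as a ratio with its exact 95% counting interval.

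A set of 21 gene lists (654 entries, of which 534 were found) was fixed before the data were examined: spermatogonia, meiotic synapsis and recombination, pachytene-expressed genes, acrosome and sperm-egg fusion, spermatid nuclear condensation, sperm flagellum and axoneme, m6A machinery, H3K9 methylation with SETDB1 partners, G1/S and DNA replication, G2/M and division, piRNA pathway, cytoplasmic ribosomal proteins, oxidative phosphorylation, glycolysis in its somatic forms, handling and dissociation stress, Sertoli cells, Leydig cells, peritubular myoid cells and fibroblasts, endothelium, macrophages and leukocytes, and erythrocytes. Lists of at least 5 tested genes and the X-linked genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with the correlation estimated from the data. The fixed lists were adjusted together over lists and comparisons, and the X-linked genes apart, over their 3 comparisons. Camera sets a list against the other genes, while fry, an alternative, sets it against no change. Under the estimated correlation 0 of 63 list tests passed.

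Peaks carry the gene named in the lists, matched to the expression table by gene ID or name. A gene counted as methylated in a library with at least 1 peak. Where peaks and expression were compared within libraries, the MeRIP-seq and RNA-seq libraries of the same short name were paired. Numbers of peaks and genes were compared over the cell types with an exact permutation of an F statistic over all 1680 labelings. Overlap of peaks (at least 1 bp, bedtools 2.31.1) was given as a Jaccard index. Gain and loss meant a peak in 3 of 3 libraries of a cell type and 0 of 3 of another. Fixed lists were compared with all genes of at least 1 FPKM by Fisher's exact test, adjusted over lists and cell types, and genes gaining or losing a peak were tested with camera, adjusted over the 6 sets, and set against 10000 random lists matched on mean expression. The permutation and counting code was checked on made-up tables with known answers. Sequence motifs and gene regions were not analysed here, as no genome or annotation of the build was at hand. Position is given along the gene locus, introns included, a measure chosen after the data were seen.

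The genes named in each expression comparison follow a rule fixed before the data were examined. It takes the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 5 FPKM over the 9 libraries and no overlap between the groups' libraries. From each list it takes up to 3 called members with the smallest adjusted p and the member with the highest mean FPKM, and it always takes SETDB1, METTL3, METTL14, WTAP, FTO, ALKBH5, YTHDF1 to YTHDF3, YTHDC1 and YTHDC2. For m6A it ranks genes by their best peak in the library where its fold enrichment is lowest. It takes the 6 highest among those with peaks in a single cell type and a mean of at least 1 FPKM in each, the 6 highest among genes with peaks in all 9 libraries, and up to 3 members per list with a peak in 3 of 3 libraries of a cell type and 0 of 3 of another. Not every gene under the rule is named. Members named because they moved against their list, or because they make up a small count, were chosen after their values were seen.

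Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter and a filter at 5 FPKM, quantile and median scaling, DESeq2 1.42.0, a fit on the 6 libraries compared, no fold limit, a replicate block, other set tests, the upper part of each peak list and equal numbers of top peaks, reciprocal overlap of 50%, and leaving out each library. Chosen after the data were seen were limma at a pseudocount of 1, RLE scaling, total-count scaling, list tests without pachytene library 2 and fry for X-linked genes. Total-count scaling divided each library's deposited estimated counts by their total over the tested genes, without a further factor. This division cancels the authors' factor for each library, so these values are not on the authors' scale. The tools ran in R 4.3.3 and python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.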

Results

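Gene expression and N6-methyladenosine (m6A), the most common internal modification of messenger RNA, were measured in purified pig male germ cells of 3 types. Spermatogonia are the mitotic germ cells, pachytene spermatocytes are in the long prophase of the first meiotic division, and round spermatids are the haploid cells that go on to form sperm. Each cell type had 3 RNA-seq libraries and 3 MeRIP-seq libraries, in which RNA fragments carrying m6A are enriched by immunoprecipitation, so that 18 libraries were analysed. The RNA-seq libraries held 3535062 to 3951959 fragments on annotated genes in spermatogonia, 4198161 to 5410510 in pachytene spermatocytes and 4044107 to 5016117 in round spermatids. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

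The RNA-seq libraries separated by cell type, with pachytene spermatocyte library 2 standing apart from the other libraries of its type. Principal component 1 carried 55.8% of the variance and component 2 carried 33.2%. Pearson's r of log2(FPKM + 1) across genes was 0.960 to 0.964 among spermatogonia and 0.966 to 0.972 among round spermatids. Pachytene libraries 1 and 3 correlated at 0.965, but library 2 correlated with them at 0.887 and 0.894 and with the spermatogonia at 0.889 to 0.912. Genes are not independent replicates, so these coefficients only describe the libraries. Of 13698 tested genes, 9306 differed between the cell types (edgeR F-test, adjusted p below 0.05). Of these, 3857 had their highest mean FPKM in spermatogonia, 2568 in pachytene spermatocytes and 2881 in round spermatids. These numbers rest on the FPKM scale, which differs from the scale tested.

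**Figure D1:**
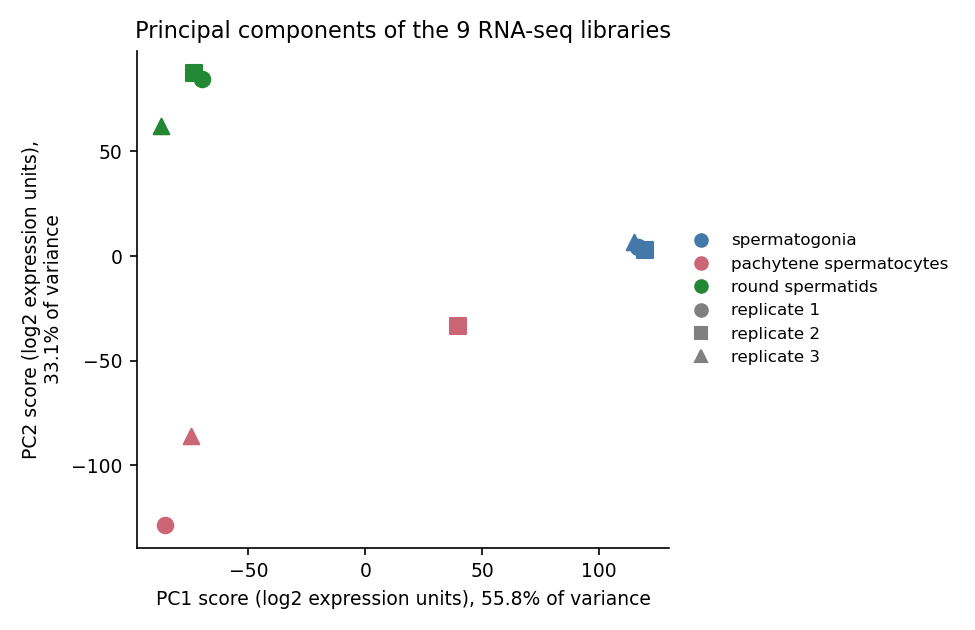
Principal components of log2 library-scaled fragments (TMM) in the 9 RNA-seq libraries, with component 1 (55.8% of the variance) on the horizontal and component 2 (33.2%) on the vertical axis and each point a library coloured by cell type. Pachytene spermatocyte library 2 lies at 39.5 on component 1, between the other pachytene libraries (-85.6 and -74.5) and the spermatogonia (115 to 120).

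The comparison of pachytene spermatocytes with spermatogonia asks which transcripts change as mitotic germ cells enter meiosis. More genes rose than fell in the lists of the sperm flagellum, the acrosome, meiotic recombination, cell division and the piRNA pathway, and more fell than rose among X-linked genes, Sertoli cell markers and ribosomal protein genes. With an estimated correlation none of these sets passed. CATSPERB, an auxiliary subunit of the sperm calcium channel (chromosome 7, 119753898 to 119806157 in susScr3), rose from 4.26 ± 0.251 to 141 ± 73.8 FPKM (mean ± SD, n = 3), a log2 fold change of 5.64 (SE 0.574, adjusted p = 0.000105). CCDC38, a coiled-coil protein gene (chromosome 5, 91781024 to 91817365), rose from 4.28 ± 0.192 to 146 ± 70.6 FPKM, a log2 fold change of 5.69 (SE 0.530). The other rises among the largest 6 were C1orf167 (6.13), SLC9C1, a sodium/proton exchanger of sperm (5.92), FEZF1, a zinc finger transcription factor (5.60), and GNMT, glycine N-methyltransferase. GNMT had 314 fragments in the pachytene libraries and 2 in the spermatogonia, a ratio of 122 (95% counting interval 33.4 to 1010).

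Among the 6 largest falls, CLDN6, a tight junction protein, went from 15.2 ± 4.55 to 1.63 ± 2.44 FPKM, a log2 fold change of -2.90 (SE 0.778, adjusted p = 0.0131), and of -5.35 without pachytene library 2. GCS fell by 2.35 on the log2 scale (adjusted p = 0.00892). The other 4 were EID1 (-2.67), RAD51D, a RAD51 paralog of homologous recombination (-2.43), MZT1, a component of the gamma-tubulin ring (-2.41), and EMP3, a membrane protein (-2.33). EID1 lost its call without pachytene library 1 or spermatogonia library 3 (adjusted p 0.0567 and 0.0769, at -2.35 and -2.30) and RAD51D without pachytene library 3 or spermatogonia library 1 (0.0596 and 0.0595, at -2.00 and -2.13). MZT1 (0.0561 to 0.121, at -2.67 to -1.97) and EMP3 (0.0705 to 0.0944, at -2.39 to -1.82) lost theirs without pachytene library 1 or 3 or any spermatogonia library. With pachytene library 2 left out EID1 stood at -4.99, RAD51D at -4.42 and EMP3 at -5.39.

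Of 39 tested genes of the sperm flagellum and axoneme, 35 rose and 0 fell (camera adjusted p = 3.3e-21, adjusted p = 0.271 with an estimated correlation). MEIG1, needed for assembly of the flagellum, rose from 16.3 ± 5.87 to 283 ± 90.0 FPKM (log2 fold change 4.70), CATSPERG by 4.49 and ODF4, an outer dense fibre protein, by 4.24. Acrosome and sperm-egg fusion genes rose in 21 of 28 with 0 falls (adjusted p = 7.5e-08, adjusted p = 0.295 with an estimated correlation), among them CRISP2, from 70.5 ± 9.69 to 1186 ± 420 FPKM (4.67), and IZUMO4 (4.45). Genes of spermatid nuclear condensation rose in 16 of 21 (adjusted p = 5.2e-05, adjusted p = 0.353 with an estimated correlation), including the testis-specific kinase TSSK3 (4.18) and BRDT, a bromodomain protein of spermatogenic chromatin (3.64). The chromatin remodeller gene CHD5 fell (-1.28), a call lost without pachytene library 1 or 3 or any spermatogonia library (adjusted p 0.0504 to 0.0657, and a log2 fold change of -0.91 without pachytene library 1). Of 21 genes known from pachytene cells 18 rose and 3 fell (adjusted p = 6.5e-10, adjusted p = 0.271 with an estimated correlation). LDHC, the testis form of lactate dehydrogenase, rose from 45.6 ± 2.40 to 687 ± 244 FPKM (4.50), NME8 by 5.51 and ADAD1 by 3.37, whereas TEX101 (-1.65), CPEB1 (-1.62) and the cyclin gene CCNB3 (-1.54) fell. CPEB1 lost its call without pachytene library 3 (adjusted p = 0.0547), stood at -2.58 without library 2, and CCNB3 lost its call without pachytene library 1 or 3 or spermatogonia library 1 or 2 (adjusted p 0.0544 to 0.0712).

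Synapsis and recombination genes rose in 13 of 29 with 0 falls (adjusted p = 0.00253, adjusted p = 0.406 with an estimated correlation). The synaptonemal complex gene SYCE1 rose by 3.37, HORMAD2, which marks unsynapsed axes, by 2.95, and STAG3, a meiotic cohesin, by 2.27, to 359 ± 122 FPKM. The falls were 3 in this list and 3 in the piRNA list without pachytene library 2, with 16 and 17 rises. Of 24 piRNA pathway genes 16 rose (adjusted p = 5.1e-05, adjusted p = 0.368 with an estimated correlation), with PIWIL1, a PIWI protein of pachytene piRNAs, at 31.1 ± 4.76 in spermatogonia and 371 ± 183 FPKM in pachytene spermatocytes (4.19), TDRD6 (3.77) and the germ cell helicase DDX4 (3.12). Division (G2/M) genes rose in 23 of 30 with 0 falls (adjusted p = 2.6e-09, adjusted p = 0.397 with an estimated correlation), such as the checkpoint kinase TTK (3.88) and PKMYT1, an inhibitory kinase of CDK1 (3.70). G1/S and DNA replication genes went both ways, with 5 rises, led by CDK2 (3.11), and 10 falls among 29. Spermatogonial markers fell in 12 of 29 (adjusted p = 0.0234, adjusted p = 0.474 with an estimated correlation), and in 20 without pachytene library 2. The 4 that rose were LHX1 (2.57), DNMT3B, a de novo DNA methyltransferase (1.55), POU3F1 (1.49) and SOHLH2 (1.33). POU3F1 lost its call without pachytene library 1 or spermatogonia library 1 or 3 (adjusted p 0.0517 to 0.0821). With total-count scaling LHX1 alone of the 4 passed.

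Cytoplasmic ribosomal protein genes fell in 16 of 63 (adjusted p = 7.6e-05, adjusted p = 0.560 with an estimated correlation), and in 34 without pachytene library 2. RPS12, the most abundant, stood at -0.78 (adjusted p = 0.0306), below the 2-fold limit, and RPL10 rose (3.60), at a short locus on chromosome 1. Near-identical copies of ribosomal protein genes can share reads, so single members are uncertain. Of 16 glycolysis genes in their somatic forms 10 fell, such as the pyruvate kinase gene PKM (-1.28), and PFKM (2.13) and LDHA (1.71) rose. The list had adjusted p = 0.0597, and without pachytene library 2 0.00655 (adjusted p = 0.143 with an estimated correlation). Oxidative phosphorylation genes had 9 rises, led by COX7A2 (2.64), and 3 falls among 44, and their median log2 fold change of 0.31 was negative under 3 of 6 other scalings. Handling and dissociation stress genes had 2 rises, including the chaperone gene DNAJB1 (3.05), and 2 falls among 15. Oxidative phosphorylation genes had 10 rises and 7 falls without pachytene library 2, and stress genes 2 rises and 5 falls.

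Of 13 Sertoli cell markers 10 fell (adjusted p = 0.00582, adjusted p = 0.475 with an estimated correlation). CLU, a secreted chaperone abundant in Sertoli cells, went from 696 ± 36.5 to 163 ± 197 FPKM (-1.90, and -3.36 without pachytene library 2), and lost its call without pachytene library 3 or any spermatogonia library (adjusted p 0.0525 to 0.0859). Peritubular and fibroblast markers fell in 8 of 22 (adjusted p = 0.00582, adjusted p = 0.490 with an estimated correlation), among them PDGFRB, a growth factor receptor (-1.51). Leydig cell markers fell in 5 of 13, and in 8 without pachytene library 2, among them the testosterone-forming enzyme HSD17B3 (-1.95). Endothelial markers rose in 3 of 15, such as NOS3 (1.78), with a median of 0.40 that was negative under 2 of 6 other scalings. Of 14 macrophage and leukocyte markers ITGAM fell (-1.66), a call lost without pachytene library 1 or 3 or any spermatogonia library (adjusted p 0.0701 to 0.116), and of 4 erythrocyte genes HBA fell (-1.24). Macrophage markers fell in 4 without pachytene library 2, ITGAM by 3.04, and of the erythrocyte genes 2 fell and 1 rose. Mean log2(FPKM + 1) of the Sertoli list was 4.43 to 4.77 in spermatogonia and 1.88, 3.88 and 2.41 in pachytene libraries 1 to 3. RNA of whole fractions does not show which cells these transcripts came from, so part of the falls may not be of germ cells.

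SETDB1, a histone H3 lysine 9 (H3K9) methyltransferase (chromosome 4, 107508697 to 107547726), rose from 45.8 ± 2.79 to 83.8 ± 17.5 FPKM. Its log2 fold change was 1.45 (SE 0.325, edgeR adjusted p = 0.00554), and 0.70 with total-count scaling. Of 17 genes of H3K9 methylation 5 rose, led by ATF7IP2, a binding partner of SETDB1 (3.29), and KDM4B, a demethylase, fell (-1.45). The call of KDM4B was lost without pachytene library 3 or spermatogonia library 1 (adjusted p 0.0647 and 0.0519), and its log2 fold change was -2.20 without pachytene library 2. The list's median of 0.56 was negative under 2 of 6 other scalings. Of 21 m6A genes 5 rose, with MEIOC (listed as C17orf104), a partner of YTHDC2, at 3.18, and 5 fell, including the reader genes IGF2BP1 (-2.02, to 12.1 ± 15.9 FPKM) and IGF2BP2 (-2.03, to 4.86 ± 4.51 FPKM), at -3.68 and -3.52 without pachytene library 2. Both of these calls were lost without pachytene library 3 or spermatogonia library 1 or 3, and IGF2BP1 also without spermatogonia library 2 (adjusted p 0.0519 to 0.0804). The methyltransferase genes METTL3 (0.39, edgeR adjusted p = 0.23) and METTL14 (-1.40, adjusted p = 0.0521) did not pass. Nor did their partner WTAP (-0.59, adjusted p = 0.0711) or the readers YTHDF2 (-0.17, adjusted p = 0.528) and YTHDC2 (0.67, adjusted p = 0.0834). METTL3 was negative with total-count scaling. FTO, ALKBH5, YTHDF1, YTHDF3 and YTHDC1 were not found by name in the expression table and their expression was not analysed here.

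At an adjusted p below 0.05 and at least 2-fold, 3216 genes rose and 2925 fell (edgeR quasi-likelihood test). Adjusted over the list alone, the counts of risen and fallen genes were the same in every list but nuclear condensation (17 and 1), G1/S (6 and 10), G2/M (24 and 0), piRNA (16 and 2) and macrophage (0 and 0). With total-count scaling, under which the median of all genes lay 0.61 lower, 1826 rose and 4191 fell. With limma on log2(FPKM + 1) the numbers were 1969 and 4732, with the lower pseudocount 2094 and 5066, and with median scaling 2425 and 3948. The falls depend most on which libraries enter the fit: with spermatogonia and pachytene libraries alone 2801 rose and 145 fell. Leaving out pachytene library 3 gave 3160 calls with 495 falls, and leaving out pachytene library 1 gave 3941 with 1260. Without spermatogonia library 1 or 3 there were 3726 with 1071 and 3863 with 1154. Without pachytene library 2 there were 8423, with 3736 rises and 4687 falls.

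**Figure D2:**
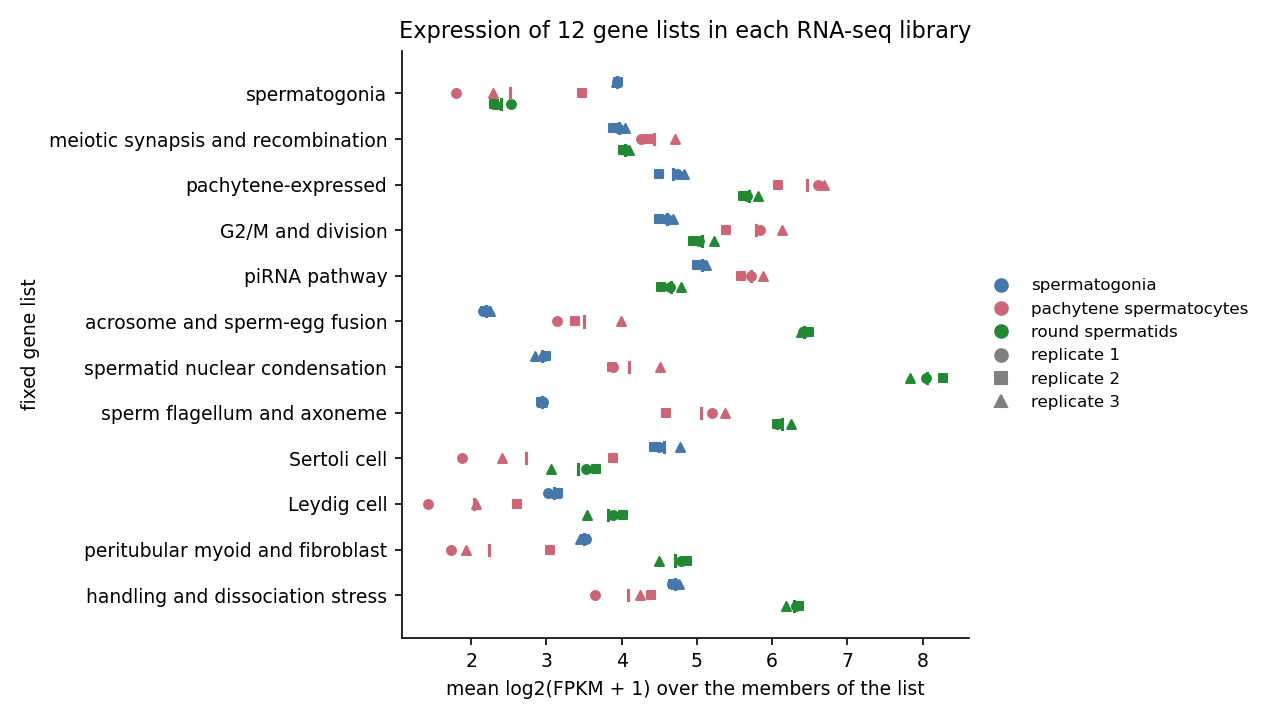
Mean log2(FPKM + 1) (horizontal axis) over the members of 12 fixed gene lists (vertical axis) in the 9 RNA-seq libraries. Points are libraries coloured by cell type, and bars mark the mean of 3. In the comparison of round spermatids with pachytene spermatocytes acrosome genes rose in 23 of 28 and peritubular markers in 20 of 22. The values are on the authors' FPKM scale. On log2(FPKM + 1) the median log2 fold change of all genes differs by up to 0.32 from that of the fit used in testing.

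The comparison of round spermatids with pachytene spermatocytes follows the germ cells out of meiosis. More genes rose than fell in the lists of sperm nuclear packaging, of the acrosome and of interstitial, vessel and blood cells and handling stress, and more fell than rose in those of the piRNA pathway, division and meiotic synapsis. With an estimated correlation none of these lists passed. PRM1, protamine 1, which replaces histones in the sperm nucleus (chromosome 3, 32650624 to 32650882), rose from 27.8 ± 13 to 4366 ± 938 FPKM, a log2 fold change of 7.36 (SE 0.506, adjusted p = 2.4e-06). TNP1, transition protein 1, rose from 86.9 ± 43.6 to 7188 ± 1430 FPKM (6.28). PIWIL1 fell from 371 ± 183 to 28.8 ± 1.30 FPKM, a log2 fold change of -3.92 (SE 0.463, adjusted p = 8.7e-05).

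The other 5 of the largest rises were HBB, a beta-like globin (7.86, to 179 ± 60.5 FPKM, with all 5 of its pachytene fragments in library 3), TMEM239 (7.07), and CST8, a cystatin of the male tract, NUPR1L and CIMAP1C, which had 1 fragment each in the pachytene libraries and ratios of 344 (95% counting interval 61.2 to 13600), 343 (61.0 to 13600) and 215 (38.1 to 8530). Beside PIWIL1, the largest falls were TDRD6 (-4.05, from 232 ± 102 to 16.7 ± 0.715 FPKM), the small GTPase gene RHOV (-3.80), PKMYT1 (-3.79), the mitotic kinase gene PBK (-3.71) and SALL4, a transcription factor of spermatogonia (-3.43).

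Spermatid nuclear condensation genes rose in 17 of 21 with 0 falls (camera adjusted p = 9.8e-25, adjusted p = 0.123 with an estimated correlation). SPEM1, needed for shaping of the sperm head, rose from 2.87 ± 0.396 to 333 ± 86.6 FPKM (6.72), OAZ3, an antizyme of haploid cells, by 6.5 and the kinase gene TSSK6 by 6.25. Acrosome genes rose in 23 of 28 with 0 falls (adjusted p = 4.4e-17, adjusted p = 0.142 with an estimated correlation), such as SPPL2C (6.17) and ACTL7A, an actin-like protein of the perinuclear theca (4.36). Falls appeared in 1 condensation gene and 2 acrosome genes without pachytene library 2. Flagellum genes rose in 11 of 39 and fell in 2, the dynein genes DNAH2 (-1.89) and DNAI2 (-1.37) (adjusted p = 0.00462, adjusted p = 0.566 with an estimated correlation). Without pachytene library 2, 8 fell, with adjusted p = 0.467 and a median of -0.19 in place of 0.12. DNAI2 lost its call without pachytene library 1 or 3 or round spermatid library 1 or 2 (adjusted p 0.0645 to 0.195, and -0.74 without pachytene library 1). AKAP4, of the fibrous sheath, rose from 17.1 ± 11.4 to 1277 ± 291 FPKM (6.03), ODF1 (listed as ODFP) by 5.65 and GAPDHS, the sperm form of glyceraldehyde-3-phosphate dehydrogenase, by 5.91.

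Of 24 piRNA genes 13 fell and 0 rose (adjusted p = 1.6e-06, adjusted p = 0.280 with an estimated correlation), with TDRD1 at -3.33. G2/M genes fell in 14 of 30 (adjusted p = 5e-05, adjusted p = 0.5 with an estimated correlation), among them CKS2, a partner of CDK1 (-2.49), and CDC25B, a phosphatase that activates CDK1, rose (1.9). Synapsis genes fell in 11 of 29 (adjusted p = 0.02, adjusted p = 0.490 with an estimated correlation), such as HORMAD2 (-2.25), while the meiotic cohesin gene REC8 (2.36, from 2.18 ± 1.16 to 11.7 ± 1.85 FPKM), DMC1 (1.28) and MCMDC2 (1.13) rose. DMC1 lost its call without pachytene library 1 (adjusted p = 0.051) or any round spermatid library (0.0574 to 0.0832). MCMDC2 lost its call without pachytene library 3 (0.0651) or any round spermatid library (0.0600 to 0.122). In all, 5 synapsis genes and 1 piRNA gene rose without pachytene library 2. Pachytene-expressed genes fell in 8 of 21 and rose in 0 (camera adjusted p = 0.000471, adjusted p = 0.470 with an estimated correlation), and 1 of the list rose without pachytene library 2. The chaperone gene HSPA2 fell from 926 ± 372 to 114 ± 7.30 FPKM (-3.26). LDHC, at 687 ± 244 and 472 ± 144 FPKM, was not called (-0.74, edgeR adjusted p = 0.168). G1/S genes fell in 5 of 29, led by CDK2 (-2.75), and CDC6, which licenses replication origins, rose (1.59). These became 4 rises and 6 falls without pachytene library 2, and the list's median turned from -0.30 to 0.28. Spermatogonial markers had 6 falls, with the growth factor receptor gene RET at -2.39, and 4 rises, KIT (1.37), FOXO1 (1.16), BCL6B (2.08) and CD90 (1.60), among 29. The balance turned to 6 rises and 5 falls without pachytene library 2, with RET at -1.15, and the list's median from -0.83 to 0.42. FOXO1 lost its call without pachytene library 1 or 3 or round spermatid library 1 or 2 (adjusted p up to 0.0922, and a log2 fold change of 0.87 without pachytene library 1). BCL6B lost its call without round spermatid library 1 or 3 (0.0929 and 0.0624) and CD90 without pachytene library 3 or any round spermatid library (0.0645 to 0.122).

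Oxidative phosphorylation genes fell in 8 of 44 and rose in 0 (adjusted p = 5.1e-05, adjusted p = 0.280 with an estimated correlation), such as NDUFS2 of complex I (-1.36), and 2 rose without pachytene library 2. Of 16 glycolysis genes 4 rose, the hexokinase genes HK1 (3.71, to 222 ± 41.9 FPKM) and HK2 (2.41), TPI1 (3.29) and PGK1 (1.65), and LDHA (-1.25) and ENO2 (-1.31) fell. PGK1 and LDHA lost their calls without pachytene library 3 or round spermatid library 1 or 2 (adjusted p 0.0516 to 0.0759), PGK1 also without round spermatid library 3 (0.0508), and PGK1 stood at 2.59 without pachytene library 2. ENO2 lost its call without round spermatid library 1 or 2 (0.0839 and 0.0854) or, at -0.91, pachytene library 2. Without pachytene library 2, 10 rose and the list passed with adjusted p = 0.00408, against 0.104 with it (adjusted p = 0.143 with an estimated correlation). Of 63 ribosomal protein genes UBA52 (1.13) and RPL22 (1.16) rose, and 10 rose without pachytene library 2. UBA52 fell below 2-fold without pachytene library 3 (0.98), and RPL22 lost its call without pachytene library 1 (0.85) or 3 or round spermatid library 1 or 2 (adjusted p 0.0756 to 0.0986). The list's median was 0.05 while its test pointed down (adjusted p = 0.881), and the median was negative under 2 of 6 other scalings.

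More markers of other cells and of handling rose than fell. Peritubular and fibroblast markers rose in 20 of 22 (adjusted p = 2.3e-15, adjusted p = 0.153 with an estimated correlation), with ACTA2, smooth muscle actin, from 10.1 ± 1.53 to 163 ± 13.9 FPKM (3.88) and COL4A1, basement membrane collagen (2.99). Leydig cell markers rose in 7 of 13 (adjusted p = 0.000178, adjusted p = 0.289 with an estimated correlation), with the hormone gene INSL3 from 28.1 ± 18.2 to 615 ± 184 FPKM (4.41) and the steroid enzyme gene CYP17A1 by 3.56. Endothelial markers rose in 9 of 15 (adjusted p = 0.000132, adjusted p = 0.280 with an estimated correlation), such as ENG (2.45), and macrophage and leukocyte markers in 7 of 14 (adjusted p = 0.00194, adjusted p = 0.271 with an estimated correlation), such as the complement gene C1QC (3.62). All 4 erythrocyte genes rose, HBA from 5.97 ± 3.08 to 185 ± 41.5 FPKM (4.88), a list too short for a test. Handling and dissociation stress genes rose in 11 of 15 (adjusted p = 5.7e-11, adjusted p = 0.123 with an estimated correlation), with EGR1 at 3.24 and JUNB at 3.22. Sertoli cell markers rose in 3 of 13, CITED1 (3.22), VIM (1.62) and DEFB119 (2.42), and in 7 without pachytene library 2, with VIM at 2.67. VIM and DEFB119 lost their calls without pachytene library 1 or 3 or any round spermatid library (adjusted p 0.0502 to 0.132).

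SETDB1 fell from 83.8 ± 17.5 to 44.8 ± 7.52 FPKM, a log2 fold change of -1.10 (SE 0.322, adjusted p = 0.0229). The call was lost without round spermatid library 1 or 2 (edgeR adjusted p 0.103 and 0.101) or pachytene library 1 or 3 (0.0594 and 0.0616). The fold was under 2 with total-count scaling (-0.86). Of 17 H3K9 genes 4 fell, with CBX5, heterochromatin protein 1 alpha, at -2.05, and the list passed without pachytene library 2 (adjusted p = 0.0220, against 0.0805), but not with an estimated correlation as well (0.237). Of 21 m6A genes RBM46 (-1.65), IGF2BP1 (-3.36, and -1.71 without pachytene library 2) and MEIOC (C17orf104, -1.53) fell and RBMX rose (1.53), and 5 fell and 2 rose without pachytene library 2. MEIOC lost its call without pachytene library 3 or round spermatid library 1 or 2 (adjusted p 0.0820 to 0.0995, and -0.87 without pachytene library 3). METTL3 stood at -0.90 (adjusted p = 0.0271), under the 2-fold limit, METTL14 at 0.19, WTAP at 0.70, YTHDF2 at -0.23 and YTHDC2 at -0.53 (adjusted p 0.0595 to 0.823), and METTL14 was negative under quantile normalization and without pachytene library 1.

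In this comparison 2225 genes rose and 1422 fell, and with limma on log2(FPKM + 1) 2344 rose and 905 fell. Adjusted over the list alone, the counts of risen and fallen genes differed in spermatogonia (6 and 6), synapsis (4 and 12), pachytene-expressed (0 and 9), nuclear condensation (17 and 1), flagellum (11 and 3), H3K9 (0 and 2), G2/M (1 and 15), ribosomal proteins (0 and 0), glycolysis (4 and 3), Leydig (8 and 0), endothelial (11 and 0) and macrophage lists (8 and 0). Without pachytene library 2 there were 5985 calls, and without round spermatid library 1 or 2 the falls numbered 796 and 797.

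The comparison of round spermatids with spermatogonia spans the whole series. More genes of the sperm head, the acrosome and the flagellum rose than fell, and more spermatogonial markers fell than rose. These lists did not pass with an estimated correlation. CLDND2, a claudin-like membrane protein, TEPP, TSPAN16, a tetraspanin, and MGP, matrix Gla protein, had 0 fragments in the spermatogonia and were at least 108-fold, 80.7-fold, 77.6-fold and 65.1-fold higher in round spermatids, counted against a floor of 3 fragments over the group, with CLDND2 at 70.3 ± 9.11 FPKM. ANXA13, an annexin, rose by 9.19 (SE 0.768, adjusted p = 4.5e-06), and FAM166A had 1222 against 2 fragments, a ratio of 521 (95% counting interval 144 to 4310). IGF2BP1, an mRNA-binding protein of proliferating cells (chromosome 12, 25163100 to 25209807), fell from 59.5 ± 2.51 to 1.09 ± 0.190 FPKM, a log2 fold change of -5.38 (SE 0.763, adjusted p = 0.0002).

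Other large falls were RLBP1, a retinaldehyde-binding protein (-5.67), NANOS3, a translational repressor of germ cells (-5.20, from 43.2 ± 2.64 to 0.904 ± 1.15 FPKM), SALL4 (-5.19, from 29.7 ± 1.86 to 0.656 ± 0.333 FPKM) and TMEM55A (-4.30). RPRML had 52 fragments in spermatogonia and 1 in round spermatids, a ratio of 61.0 (95% counting interval 10.5 to 2450). Spermatogonial markers fell in 16 of 29 (camera adjusted p = 0.0036, adjusted p = 0.432 with an estimated correlation), including RET (-4.20) and the ubiquitin hydrolase gene UCHL1 (-3.32). STRA8, which acts at meiotic entry (2.10), and BCL6B (2.14) rose, the latter not without spermatogonia library 3 or round spermatid library 1 (adjusted p 0.0638 and 0.0518). Spermatogonial markers that rose numbered 4 without pachytene library 2.

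Nuclear condensation genes rose in 19 of 21 with 0 falls (adjusted p = 7.7e-27, adjusted p = 0.123 with an estimated correlation), with SPEM1 at 8.04, OAZ3 at 8.01 and TNP1 at 7.66. Acrosome genes rose in 27 of 28 (adjusted p = 7.7e-27, adjusted p = 0.142 with an estimated correlation), with SPPL2C at 7.38 and CRISP2 at 6.0, to 3486 ± 478 FPKM. Flagellum genes rose in 38 of 39 (adjusted p = 9.2e-25, adjusted p = 0.248 with an estimated correlation), with AKAP4 at 8.16, ODF1 at 7.17 and ROPN1, a fibrous sheath protein, at 5.41. With members at 0 in spermatogonia held at their lower bound the medians of the condensation and acrosome lists were 6.86 and 5.18. Pachytene-expressed genes rose in 12 of 21 (adjusted p = 0.0109, adjusted p = 0.539 with an estimated correlation), such as LDHC (3.77), and CCNB3 (-2.31) and CPEB1 (-1.84) fell. Of 29 synapsis genes 9 rose, such as SYCE3 (2.96), and MND1 (-1.92), BRME1 (listed as C19orf57, -1.76), REC114 (-2.10) and TEX12 (-1.40) fell. The call of TEX12 was lost without any 1 of the 6 libraries (adjusted p 0.0551 to 0.123).

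Of 30 G2/M genes 14 rose and 0 fell, with PTTG1, securin, at 2.74, and the list's adjusted p was 0.0865 (0.0303 without pachytene library 2, which enters through the shared spread, and 0.482 there with an estimated correlation). G1/S genes fell in 8 of 29 (adjusted p = 0.0272, adjusted p = 0.271 with an estimated correlation), such as RPA1 (-1.93), while CCNE1 (2.02) and CHAF1A (1.56) rose. Of 24 piRNA genes 6 rose, with DDX4 at 2.46, and 6 fell, with TDRD1 at -1.68. The list's median of 0.16 was negative under 4 of 6 other scalings while its mean and its test pointed down (adjusted p = 0.663). Ribosomal protein genes fell in 13 of 63 (adjusted p = 0.000369, adjusted p = 0.566 with an estimated correlation), such as RPL14 (-1.36). Oxidative phosphorylation genes fell in 10 of 44 (adjusted p = 0.0245, adjusted p = 0.490 with an estimated correlation), with ATP5A1 of the ATP synthase at -1.70, and COX7A2 (2.21), ATP5F1 (1.33) and NDUFB3 (1.02) rose. The call of NDUFB3 was lost without spermatogonia library 1 or 2 or any round spermatid library (adjusted p 0.0509 to 0.107). Glycolysis genes had 5 rises, led by HK1 (2.86), and 4 falls among 16, and 5 rises and 6 falls without pachytene library 2.

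Stress genes rose in 14 of 15 (adjusted p = 3e-07, adjusted p = 0.172 with an estimated correlation), with EGR1 at 3.07. Peritubular markers rose in 13 of 22 (adjusted p = 3e-05, adjusted p = 0.353 with an estimated correlation), with ACTA2 at 4.67, and the matrix gene POSTN fell (-2.86), but not without round spermatid library 2 (adjusted p = 0.0578). Endothelial markers rose in 12 of 15 (adjusted p = 5.2e-05, adjusted p = 0.271 with an estimated correlation), with ENG at 2.86. Leydig markers rose in 7 of 13, with INSL3 at 3.13, and HSD17B3 (-1.69) and IGFBP3 (-1.59) fell. Macrophage markers rose in 7 of 14, with C1QC at 4.47, and MRC1 fell (-2.24), with 2 falls without pachytene library 2. HSD17B3 lost its call without spermatogonia library 1 or round spermatid library 2 or 3 (adjusted p 0.0521 to 0.0541). IGFBP3 lost its call without any spermatogonia library or round spermatid library 1 or 3 (0.0511 to 0.105) and MRC1 without round spermatid library 2 or 3 (0.0736 and 0.0724). Of 4 erythrocyte genes 3 rose, and HBB had 1248 against 3 fragments, a ratio of 355 (95% counting interval 121 to 1720). Sertoli markers went the other way, with 5 of 13 falling, CLU at -3.24 and the junction gene CLDN11 at -3.21, and DEFB119 rising (3.96, with all 4 of its spermatogonial fragments in library 3). The list passed without pachytene library 2 (adjusted p = 0.00751, against 0.0715), with 7 falls, but not with an estimated correlation as well (0.327).

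SETDB1 stood at 44.8 ± 7.52 FPKM in round spermatids and 45.8 ± 2.79 in spermatogonia (0.35, adjusted p = 0.381), a value that was negative under 3 of 6 other scalings. Of 17 H3K9 genes ATF7IP2 (2.21) and PPHLN1 (1.26) rose and CBX3 (-1.26) and CBX1 (-1.17), heterochromatin proteins, fell. The list's median of 0.30, negative under 3 of 6 other scalings, differed in sign from the test (adjusted p = 0.806). Of 21 m6A genes IGF2BP1, IGF2BP2 (-2.97), ZC3H13, a partner of the methyltransferase complex (-1.79), and FMR1 (-1.90) fell and METTL5 (1.41), MEIOC (1.65) and PRRC2A (1.33) rose. The list passed without pachytene library 2 (adjusted p = 0.0404, against 0.0798), but not with an estimated correlation as well (0.340). PPHLN1 lost its call without any 1 of the spermatogonia libraries and PRRC2A without spermatogonia library 1 or 2 or round spermatid library 3 (adjusted p 0.0511 to 0.0605). METTL3 (-0.51), METTL14 (-1.21), WTAP (0.11), YTHDF2 (-0.40) and YTHDC2 (0.14) did not pass (edgeR adjusted p 0.0879 to 0.75). WTAP and YTHDC2 were negative with total-count scaling.

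Here 3440 genes rose and 2510 fell. Under total-count scaling the median of all genes lay 0.49 lower (and 0.11 higher in the comparison of round spermatids with pachytene spermatocytes). With it 2475 genes rose and 3632 fell. With limma on log2(FPKM + 1) the numbers were 2663 and 3637, with the lower pseudocount 2660 and 3324, and with quantile normalization 2858 and 3582. Adjusted over the list alone, the counts of risen and fallen genes differed in the spermatogonia (3 and 16), acrosome (28 and 0), oxidative phosphorylation (3 and 9), peritubular (15 and 1) and endothelial lists (13 and 0). Without round spermatid library 3 the falls numbered 1598.

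X-linked genes stood lower in pachytene spermatocytes than in either other cell type. Of 484 tested X-linked genes 260 fell and 14 rose from spermatogonia to pachytene spermatocytes, and 139 rose and 3 fell from pachytene spermatocytes to round spermatids. The median log2 fold change of X-linked genes minus that of autosomal genes was -1.25 for pachytene spermatocytes against spermatogonia (camera adjusted p = 6.8e-14, adjusted p = 0.601 with an estimated correlation), 0.84 for round spermatids against pachytene spermatocytes (adjusted p = 8.4e-08, adjusted p = 0.601) and -0.62 for round spermatids against spermatogonia (adjusted p = 0.0363, adjusted p = 0.751), where 114 fell and 69 rose. Within libraries the X-linked median of log2(FPKM + 1) lay 0.61 below the autosomal one in pachytene library 2 and 1.41 and 1.28 below it in libraries 1 and 3. Without library 2 the first 2 differences were -1.98 and 1.46, with 362 falls and 308 rises. The count of falls depends on the fit. Over all genes 145 fell in the first comparison with its 6 libraries fitted alone, and 495 without pachytene library 3. With the 6 libraries alone fewer than 260 X-linked genes were therefore called as falling. The first difference itself lay between -1.98 and -0.92 with 1 library left out. Adjusted over the list alone 278 X-linked genes fell and 14 rose in the first comparison, 141 rose and 3 fell in the second and 67 rose and 108 fell in the third. Camera p-values of X-linked genes were adjusted over their 3 tests alone, which leaves the third, the largest, at its unadjusted value. The third difference lost its call without round spermatid library 3 (-0.54, camera adjusted p = 0.0760).

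**Figure D3:**
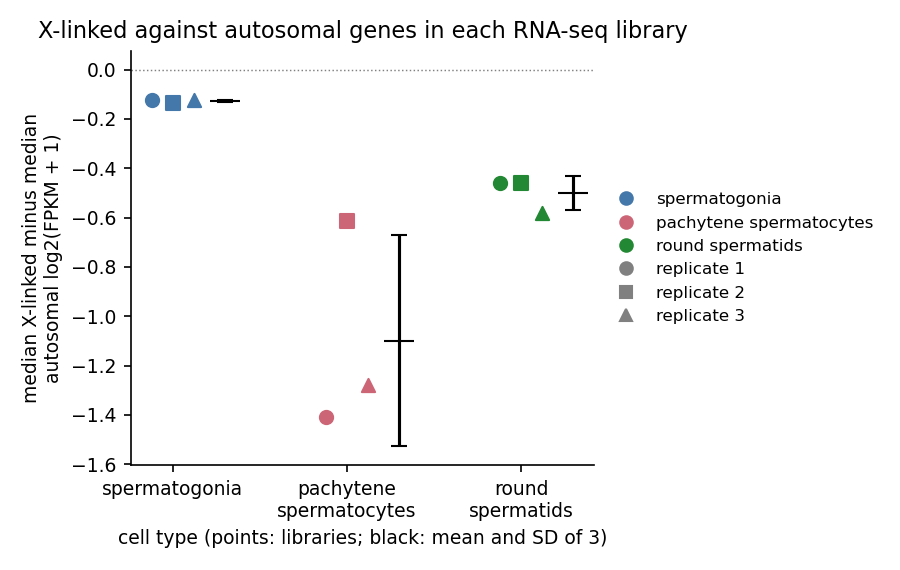
Median log2(FPKM + 1) of X-linked genes minus that of autosomal genes in each RNA-seq library (vertical axis, log2 units) by cell type (horizontal axis), with points for libraries and the mean and SD of 3. Spermatogonia lie between -0.13 and -0.12, round spermatids between -0.58 and -0.46 and pachytene spermatocytes at -1.41, -0.61 and -1.28.

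The MeRIP-seq libraries ask how m6A is placed on transcripts in each cell type. Spermatogonia had 11999 ± 901 peaks per library (mean ± SD, n = 3), pachytene spermatocytes 6501 ± 299 and round spermatids 8734 ± 740 (exact permutation test over 1680 labelings, two-sided p = 0.00357, the smallest they can give). They lay on 7862 ± 548, 4598 ± 152 and 5912 ± 197 genes, and 92.3% to 93.3% of peaks matched a gene of the expression table. With an equal number of top peaks per library the gene numbers were 4750 ± 135, 4454 ± 25.7 and 4554 ± 210 (exact permutation p = 0.15). The authors' median fold enrichment per library was 9.37 to 10.1 in spermatogonia, 5.82 to 6.07 in pachytene spermatocytes and 6.31 to 8.15 in round spermatids, a value that describes each list only. Peaks of libraries of the same cell type overlapped more than those of different types, with mean Jaccard indices of 0.640 and 0.419 (exact permutation p = 0.00357).

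**Figure D4:**
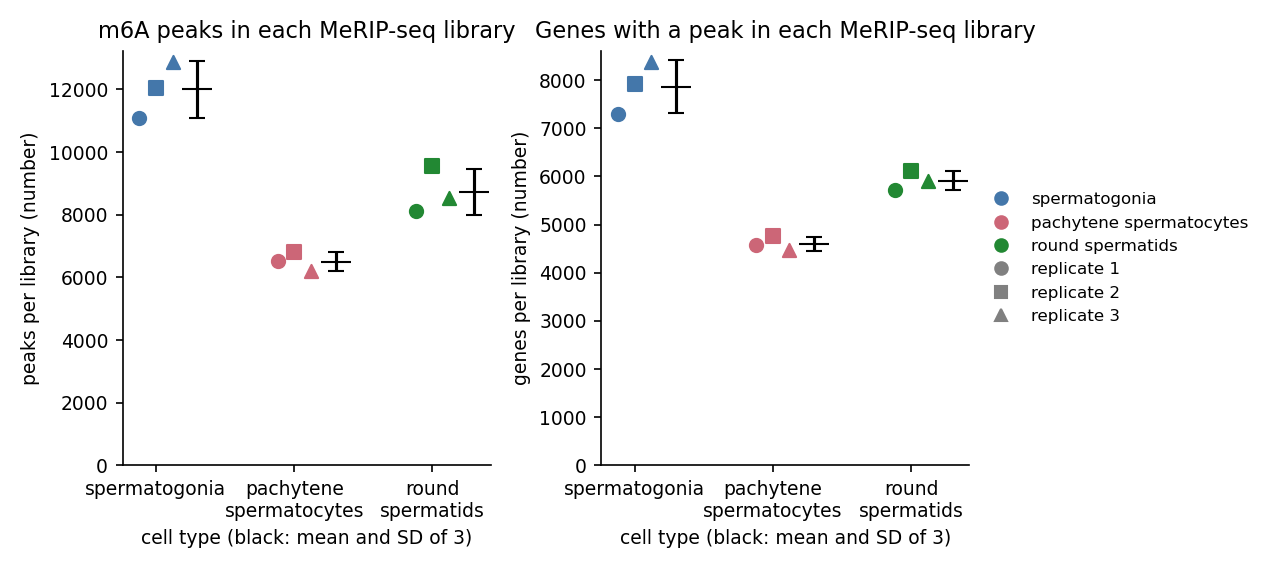
Number of m6A peaks (left) and of genes with a peak (right) in the 9 MeRIP-seq libraries by cell type, with points for libraries and the mean and SD of 3. Spermatogonia have 11079 to 12880 peaks, above all pachytene spermatocyte (6199 to 6797) and round spermatid libraries (8110 to 9552).

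More peaks lay in the last 10% of the gene locus than in any other 10%. No expected share was computed and the locus includes introns, so this does not show an enrichment at the 3′ end of transcripts. The last 10% of the locus held 37.1% ± 0.3 of peaks in spermatogonia, 32.8% ± 1.16 in pachytene spermatocytes and 32.7% ± 0.834 in round spermatids (n = 3, exact permutation p = 0.0321), and the first 10% held 16.4% ± 0.6, 15.7% ± 1.26 and 17.5% ± 0.861. Places along transcripts and sequence motifs need a genome and annotation of the build and were not analysed here.

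A core of 1966 genes carried a peak in all 9 libraries, of 10713 with a peak in at least 1. RABL6, a small GTPase (peak at chromosome 1, 313920658 to 313921357), had best peaks of 16.9 to 55.6 in the authors' fold enrichment, and TBC1D10B, BRD4, a bromodomain protein of transcription (peak at chromosome 2, 61915979 to 61916578), HSF1, the heat shock transcription factor, and TRIM44 were also among the highest in all 9 libraries. Genes with a peak in all 3 libraries of a cell type and in no other library numbered 1317 in spermatogonia, 27 in pachytene spermatocytes and 247 in round spermatids, and 541, 112 and 255 with equal numbers of peaks. In spermatogonia these included PARS2, the mitochondrial prolyl-tRNA synthetase (chromosome 6, 145656431 to 145657849, best peaks of 49.5 to 60.2 in the authors' fold enrichment), RGS10, a regulator of G protein signalling (44.6 to 72.9), and GCS (34.3 to 90.1). In pachytene spermatocytes they included PRDM16 (chromosome 6, 59709804 to 59710567, 6.07 to 9.21) and BUB1, a spindle checkpoint kinase (chromosome 3, 47576898 to 47577149, 5.45 to 7.73). In round spermatids they included C3orf22 (chromosome 13, 80923104 to 80923326, 11.1 to 67.9) and ESR1, estrogen receptor alpha (chromosome 1, 16545784 to 16546900, 9.77 to 12.4). Mean FPKM in spermatogonia, pachytene spermatocytes and round spermatids was 15.0, 3.57 and 1.74 for PARS2. It was 1.04, 5.2 and 1.85 for PRDM16 and 1.96, 3.06 and 240 for C3orf22. ESR1, at 17.2, 4.84 and 9.8, was not highest where it had its peaks. A peak can be called only where enough RNA is present, so peaks in a single cell type may follow expression.

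From spermatogonia to pachytene spermatocytes 2369 genes lost a peak (3 of 3 against 0 of 3 libraries) and 213 gained one, from pachytene spermatocytes to round spermatids 793 gained and 135 lost one, and from spermatogonia to round spermatids 480 gained and 1657 lost one. With equal numbers of peaks these were 996 lost and 607 gained, 473 gained and 240 lost, and 639 gained and 776 lost. Genes with peaks in all spermatogonia libraries and in no other included the integrin gene ITGA6, DMRT1 (listed as DMRT-1) and TAF4B of the spermatogonia list, IGF2BP1, IGF2BP2 and the piRNA gene SPOCD1. DMRT1 is also in the Sertoli cell list, and whole fractions do not show which cells carried a peak. LDHC, SPEM1 and AKAP4 had peaks in all pachytene and round spermatid libraries and in 0 of 3 of spermatogonia, and the sperm genes ACTL9, SPACA4 and HILS1 and the peritubular marker ACTA2 in round spermatids alone. CBX3 had peaks in all libraries but those of round spermatids. SETDB1 was methylated in 3, 2 and 3 libraries of spermatogonia, pachytene spermatocytes and round spermatids, with its best peak at chromosome 4, 107512257 to 107515441 (3.65 to 9.68). METTL3 had peaks in 3, 2 and 2 libraries, METTL14 in 3, 0 and 1, and WTAP and YTHDF2 in all 9.

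Against all expressed genes, 18 of 59 tests of fixed lists passed (Fisher's exact test, two-sided, a peak in at least 2 of 3 libraries), where 53.5% of expressed genes were methylated in spermatogonia, 34.3% in pachytene spermatocytes and 40.4% in round spermatids. Stress genes were methylated in 15 of 15 in spermatogonia (adjusted p = 0.00111), 11 of 14 in pachytene spermatocytes (0.00661) and 14 of 15 in round spermatids (0.000508). Of 17 H3K9 genes 16 (0.00357), 12 (0.0181) and 13 (0.0187) were methylated, and of 21 m6A genes 18 in spermatogonia (0.0181) and 13 in pachytene spermatocytes (0.0366). Flagellum genes were methylated in 24 of 37 in pachytene spermatocytes (0.00171) and 29 of 39 in round spermatids (0.000508). In pachytene spermatocytes so were condensation genes in 14 of 21 (0.0187) and G2/M genes in 18 of 30 (0.0215), and in round spermatids acrosome genes in 18 of 28 (0.0392) and peritubular markers in 16 of 21 (0.00811). Methylated below the background were ribosomal protein genes, with 17 of 62 in spermatogonia (0.000508), 11 of 63 in pachytene spermatocytes (0.0187) and 7 of 63 in round spermatids (2.6e-05), and macrophage markers in spermatogonia, with 0 of 7 (0.0187). Among genes of at least 5 FPKM 11 tests passed. The background was not matched on expression. Between the expressed genes of lowest and highest expression the share with a peak rose from 23.1% to 65.5% in spermatogonia. In round spermatids it rose from 13.7% to 59.6%. These tests therefore do not separate methylation of a list from its level of expression. Ribosomal protein genes had a mean log2(FPKM + 1) of 8.14 to 8.45 in round spermatids. Low expression does not explain their low share there.

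Methylated genes were more abundant than others. Each MeRIP-seq library was compared with the RNA-seq library of the same short name, which the labels do not say marks the same preparation. Median log2(FPKM + 1) was 1.44 ± 0.194 (SD, n = 9) higher in genes with a peak than in expressed genes without one, higher in 9 of 9 libraries (exact permutation p = 0.00391, two-sided), with 1.24 ± 0.0622 in spermatogonia, 1.57 ± 0.115 in pachytene spermatocytes and 1.52 ± 0.197 in round spermatids, 3 libraries each (exact permutation p for the difference between cell types 0.0821). A peak can be called only where enough RNA is present, so the measures are not independent.

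More genes that gained a peak rose than fell in expression, and more that lost one fell than rose. From spermatogonia to pachytene spermatocytes 153 of 169 tested genes that gained a peak rose (median log2 fold change 2.87), and 1122 of 2063 that lost one fell (-1.40). From pachytene spermatocytes to round spermatids 472 of 689 gaining genes rose (2.06) and 72 of 117 losing genes fell (-1.46), and from spermatogonia to round spermatids 368 of 398 gaining genes rose (3.82) and 751 of 1447 losing genes fell (-1.34). All 6 sets passed camera (adjusted p 1.3e-67 to 8e-18). With an estimated correlation the 2 gaining sets of round spermatids passed (adjusted p = 0.0187 against each other cell type), and the other 4 did not (adjusted p 0.0977 to 0.146). A peak can be called only where RNA is present, so gain and loss partly follow the change in expression itself. All 6 medians lay outside the central 95% of 10000 random lists, but matching these on mean expression does not remove that dependence.

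**Figure D5:**
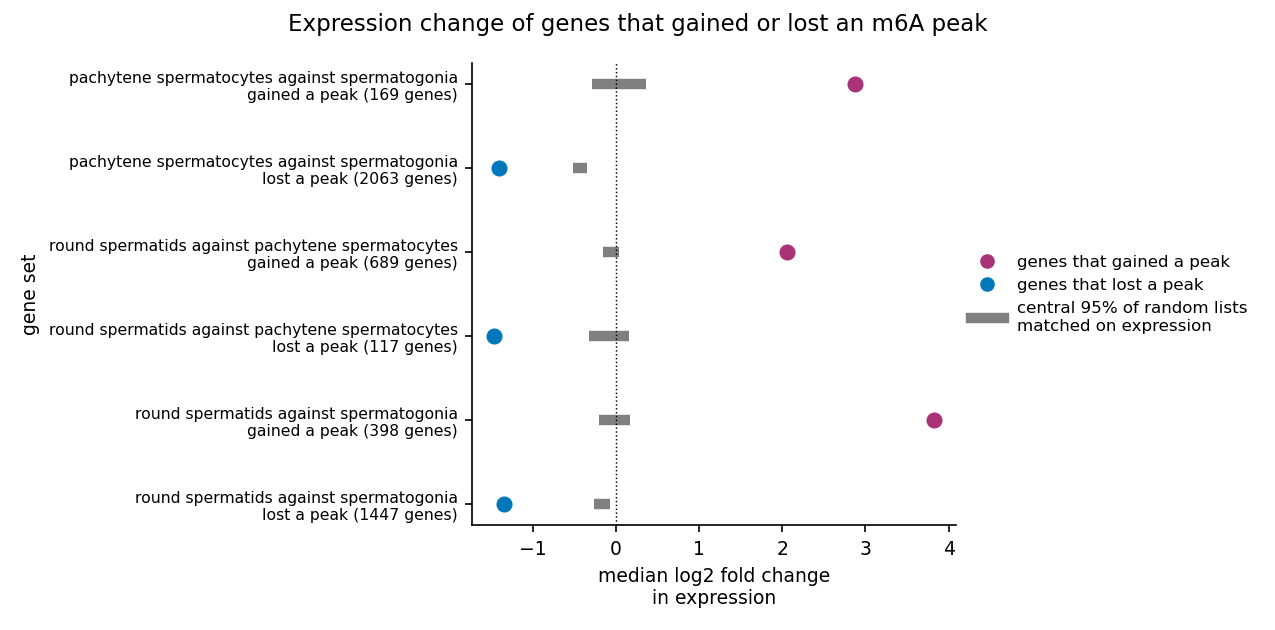
Median log2 fold change in expression (horizontal axis) of genes that gained or lost an m6A peak in each of the 3 comparisons (vertical axis), with grey bars for the central 95% of medians of 10000 random lists of the same size matched on mean expression. Gaining sets lie at 2.06 to 3.82 and losing sets at -1.46 to -1.34, outside the grey bars.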

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

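Limma at a pseudocount of 1, total-count scaling, RLE scaling, list tests without pachytene library 2 and fry for X-linked genes were chosen after the data were seen. All other alternatives were chosen before. Of 297 values recomputed for the comparisons, 271 were kept, tests by their direction and side of the threshold and counts by a total within 1.5 times. A kept total can still change its balance: pachytene spermatocytes against spermatogonia had 1826 rises and 4191 falls with total-count scaling, against 3216 and 2925. Of 207 values of genes named in the expression comparisons 189 were called. Another setting ended 43 of these calls and leaving out 1 library 37, and neither turned a sign. The falls of pachytene spermatocytes against spermatogonia numbered 145 with the 6 libraries fitted alone, against 2925.

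Counts of called genes stayed within 1.5 times under every other setting except these. For pachytene spermatocytes against spermatogonia (6141) the 6 libraries alone gave 2946 and leaving out 1 library 3160 to 8423, and for round spermatids against pachytene spermatocytes (3647) leaving out 1 library gave 2493 to 5985, highest in both without pachytene library 2. The replicate block gave 6353, 3542 and 5917 calls against 6141, 3647 and 5950. The r of deviations between libraries of the same number was 0.0633 to 0.21 for spermatogonia with pachytene spermatocytes and -0.24 to 0.16 for the other pairs. Not every library correlated best with its own number, and numbers were taken as pairs only where every r was above 0.1, so the block stayed an alternative.

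Of 63 list tests 38 passed, 0 with an estimated correlation, 45 with fry, 42 with the replicate block and 43 without pachytene library 2. The 63 pool 60 tests of fixed lists, adjusted together, and 3 of X-linked genes, adjusted apart. Without pachytene library 2 the direction of the limma set test (camera) turned for 2 lists that did not pass, ribosomal proteins in round spermatids against pachytene spermatocytes (adjusted p = 0.0772) and H3K9 genes in round spermatids against spermatogonia (0.968). The set test fry compares a list with no change and camera compares it with the other genes, so a difference between them is no turn of direction. In these same tests fry pointed up and camera down (adjusted p = 0.591 and 0.564 with fry), as for piRNA genes (0.821) and glycolysis genes (0.629) in round spermatids against spermatogonia.

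The X-linked differences of -1.25, 0.84 and -0.62 passed in 0 of 3 comparisons with an estimated correlation (adjusted p = 0.601, 0.601 and 0.751). That of round spermatids against spermatogonia did not pass with limma at a pseudocount of 1 (-0.45), at 0.1 (-0.58), with quantile normalization (-0.42) or at 5 FPKM (-0.65), and lay between -0.67 and -0.54 when 1 library was left out. Set against no change in place of autosomal genes, X-linked genes did not pass there with fry (adjusted p = 0.736). With an estimated correlation the medians of genes gaining a peak (2.87) and losing a peak (-1.40) in pachytene spermatocytes and of genes losing one in round spermatids (-1.46 and -1.34 against pachytene spermatocytes and spermatogonia) did not pass.

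With equal numbers of peaks, which fix the list length, the genes with a peak per library did not pass (exact permutation p = 0.15), genes methylated in a single cell type numbered 908 in place of 1591, and gains and losses 1603 in place of 2582 (pachytene spermatocytes against spermatogonia) and 1415 in place of 2137 (round spermatids against spermatogonia). In the upper part of each list gains and losses were 1578 in the first of these and 453 in place of 928 for round spermatids against pachytene spermatocytes. At 5 FPKM, with fewer genes, 11 in place of 18 tests of fixed lists passed. Of 31 genes named for their peaks 15 had them in fewer libraries in the upper part of the lists and 10 with equal numbers. An equal number of peaks gives no test of peaks per library, and the motif alternatives were not run for want of a genome.

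Values that were not called and changed sign are given as log2 fold changes. METTL3 in pachytene spermatocytes against spermatogonia stood at -0.29 with total-count scaling and at -0.14 and -0.15 with limma at pseudocounts of 1 and 0.1. It stood at -0.0704 with quantile normalization, and YTHDC2 at -0.0401 with total-count scaling. METTL14 in round spermatids against pachytene spermatocytes stood at -0.13 with quantile normalization and between -0.26 (without pachytene library 1) and 1.12 with 1 library left out. The values for round spermatids against spermatogonia follow the order of total-count scaling, limma at 1 and at 0.1 and quantile normalization. SETDB1 stood at -0.16, -0.0419, -0.0429 and -0.33. WTAP stood at -0.39, -0.27, -0.27 and -0.69, and at -0.0921 under median scaling. YTHDC2 stood at -0.35, -0.22 and -0.24 with the first 3 settings, and at -0.0581 under median scaling. With 1 library left out YTHDC2 stood at -0.0514 to 0.22, lowest without round spermatid library 1. Depth limits the genes of few fragments, whose fold changes carry wide intervals.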

Other observations

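The predictions for the mixture, the exchanged label, earlier spermatocytes and interstitial RNA were written before these tests were run, and those for germ cell share, list length, genes expressed and the other splits of the libraries after results were seen.

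Mitochondrial transcripts made up 3.26% to 3.91% of fragments in spermatogonia, 0.233%, 1.99% and 0.756% in pachytene libraries 1 to 3 and 1.02% to 1.67% in round spermatids. Genes of at least 1 FPKM numbered 13071 to 13279 in spermatogonia, 10001, 12668 and 10985 in pachytene libraries 1 to 3 and 12461 to 12877 in round spermatids. From the 20% of expressed genes with the lowest to the 20% with the highest expression, the share of genes with a peak went from 23.1% to 65.5% in spermatogonia, from 10.7% to 51.1% in pachytene spermatocytes and from 13.7% to 59.6% in round spermatids (means of 3 libraries).

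Pachytene library 2 lay between the other pachytene libraries and the spermatogonia. A mixture with spermatogonial RNA would give the same share from genes high in either cell type, and the shares were 0.512 (quartiles 0.465 to 0.562, 993 genes) and 0.575 (0.504 to 0.652, 472 genes), a difference of 0.0631, so this explanation may hold. An exchanged label would give a share near 1 from the second set, and 0.575 argues against it. Earlier spermatocytes were predicted to raise synapsis and recombination genes above the level of such a mixture. The median log2 ratio of these genes to it was -0.00131 (29 genes, quartiles -0.15 to 0.06). Their mean log2(FPKM + 1) was already 3.88 to 4.05 in spermatogonia, against 4.26 and 4.70 in pachytene libraries 1 and 3. Their level in earlier spermatocytes was not measured, so this does not decide. Other biological explanations, such as a fraction with more mitotic cells in that preparation, remain possible and were not tested apart from the mixture. The MeRIP-seq library of the same name had 6797 peaks, against 6508 and 6199 in pachytene libraries 1 and 3 and 11079 to 12880 in spermatogonia. The labels do not say that a shared name marks the same preparation, so these counts do not decide.

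Markers of interstitial cells and of handling stress stood higher in round spermatids than in pachytene spermatocytes. A lower share of germ cells with all other cell types alike would give lists of these types the same change, but over all members with a fragment, without a filter on low values, medians of the lowest and highest list differed by 2.499. They were 0.32 in Sertoli cells (17 genes, quartiles 0.03 to 1.60) and 2.82 in peritubular cells and fibroblasts (22 genes, 2.0 to 3.16). Without pachytene library 2 they were 1.32 (0.76 to 2.32) and 3.22 (2.53 to 3.78), 1.898 apart, and without any other library of these cell types 2.32 to 2.58 apart, with the quartiles of both lists apart each time. An equal change holds only if germ cells express none of the members, and the Sertoli marker DMRT1 is also in the spermatogonia list. Both lists were also picked for their lowest and highest medians, so the gap does not decide. RNA of interstitial cells in the round spermatid fraction remains open. Of the most abundant markers 13 of 15 rose, all but NOS3 and ITGAM, but these belong to the lists that show the pattern, so the count only repeats it and decides nothing. Transcription of such genes in the spermatids themselves could also account for single markers and cannot be told apart in RNA of whole fractions.

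Spermatogonia had more peaks and more methylated genes than pachytene spermatocytes. If the length of the lists, set by depth or enrichment, were the cause, losses and gains should be equal at equal numbers of peaks, and their ratio was 1.64 in place of 11.1, which leaves this open. Fewer expressed genes in pachytene spermatocytes would leave the percentage of expressed genes with a peak unchanged, but it was 52.3% ± 3.39 in spermatogonia and 35.9% ± 3.10 in pachytene spermatocytes (n = 3), 9.35 points apart at the closest libraries and 8.38 in the 20% of genes with the highest expression, which argues against it. These percentages rest on MeRIP-seq and RNA-seq libraries paired by their short name. A difference in methylation itself remains possible, and no spike-in or input value at hand separates it from enrichment.

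Other splits of the same libraries were compared with the real one. The real split was 1 of 10 in each expression comparison, with 6141, 3647 and 5950 calls against 0 in every other split. Without adjustment the others had at most 2072, 3866 and 48 genes. These do not compare with the calls, as no unadjusted count is given for the real split. With 10 splits a share under 0.05 cannot be reached. For any difference between the cell types 1 of 100 splits, the real one, gave 9306 genes, and the next 5406 in a split that kept the spermatogonia together. For genes methylated in a single cell type the real split of 280 gave 1591 and the next 1333, and for gains and losses 2582, 928 and 2137 against at most 63, 93 and 159 in 9 others.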
